A study of Mus musculus with 2 samples.

How the data were processed

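The series compared 2 clones of mouse mesoangioblasts, D16 and D351, on Affymetrix MG-U74B expression arrays. Mesoangioblasts are vessel-associated progenitor cells grown from embryonic aorta that can give rise to several mesodermal cell types. Per the labels' protocols, dorsal aorta of C57BL6 mouse embryos at day 9.5 was kept as an explant for 5 days, dissociated, and cloned by limiting dilution. The cloning step used RPMI with 20% fetal calf serum over embryonic mouse fibroblasts treated with mitomycin C. Growing clones were then moved to gelatin-coated dishes and expanded. Total RNA of each clone was hybridised to 1 array, so no array was replicated and the groups were the 2 clones as named in the sample titles.

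The deposited values are intensity values on a linear scale, 1 per probe set and array, as the authors processed them. They ranged from 0 to 6716.8 on the D16 array and from 0 to 4549.9 on the D351 array, with medians of 16.6 and 16.9. After trimming 2% of the values at each end, both columns had a mean of 40.0, as arrays scaled to a common target have. The software, the background correction and the presence calls were not given in the sources used here. A scaling to a common trimmed mean makes the values relative to the bulk of each array, so a difference shared by all transcripts would not be visible in them. Because the trimmed means matched within 5%, the values were used as deposited, by a rule fixed in advance.

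The table held 12477 probe sets, of which 66 were controls and were left out of the comparison. Gene names came from the platform annotation kept by GEO, which is younger than the arrays, updated through gene identifiers to NCBI RefSeq names of assembly GRCm38.p6. Of the 12411 other probe sets, 10581 had exactly 1 gene symbol, 178 had several and were not named, and 1652 were unnamed here. Identifiers of 10572 probe sets with 1 symbol matched the RefSeq table, and 0 symbols were renamed by that match. The named probe sets stood for 7542 different symbols. Chromosome and gene order were taken from that assembly, and no coordinates were used because the array files name no build. Most probe set names (10702) had the plain ending _at. The endings _f (603), _r (506), _i (418), _g (101) and _s (81) mark designs shared with related transcripts or made under relaxed rules, and the ending is given where a value rests on such a probe set.

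Values under a floor of 16.8, the pooled 50th percentile of both arrays, were raised to it before the ratio of D351 over D16 was taken on the log2 scale. A ratio with 1 array under the floor is a bound, written as at least a given fold or as a log2 ratio of at least, or at most, a given value. List and chromosome medians take such ratios at their bound. Probe sets under the floor on both arrays were given no ratio. A probe set passed the size rule when the arrays differed at least 2-fold with the brighter one at or above the floor. A gene was represented by its probe set with the highest mean signal. With 1 array per clone there is no spread between replicates, and no p-value, standard error or count of significant genes was computed.

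The genes named in the text followed a rule. Per direction these were the 12 genes with the largest ratio among those past the size rule, with 1 symbol that is not a clone or model name and with the brighter array at or above the pooled 75th percentile (53.5). From each of 26 gene and marker lists up to 6 members past the size rule were added. The array held only part of each list, such as 38 of 76 smooth muscle and actin genes and 36 of 83 Wnt genes. It held 32 of 108 matrix genes, 22 of 110 cell cycle genes and 9 of 49 embryonic fibroblast markers. A further 10 genes (Acta2, Tagln, Cnn1, Thy1, Ly6a, Cdh5, Pecam1, Ptprc, Myod1 and Myf5) were to be named at any value, and 0 of them were on this array. Other genes named here illustrate a list or a gene stretch. The median ratio of a list was placed among 10000 random lists of the same size, matched on mean log2 expression in 10 bins, and a list stood apart when it lay outside the central 95% of them. Lists with under 5 measured genes had no such placement. Chromosome medians were treated in the same way. These percentiles describe the 2 arrays and do not replace replicates. For genes with several measured probe sets, the ratios of the brightest pair were compared, with a Wilson interval at 95% for the share in one direction.

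All of these rules, the lists and the following other settings were fixed before the data were examined. These settings were scaling to a common median, quantile normalization, a loess correction (span 0.3), floors at the 25th (4.6) and 75th (53.5) percentiles, size rules of 1.5-fold and 3-fold, a minimum difference equal to the floor, the median over probe sets of a gene, and the mean of a list. Further settings were added later and are named as such in the closing section. Data were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.

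The scripts were tested on simulated data with an error of 0.5 (SD of the log2 ratio). In this simulation of D351 against D16 the size rule recovered 52.2% of 67 genes differing 2-fold, 95.5% of 67 genes differing 4-fold and 100% of 66 genes differing 8-fold. Of 6372 unchanged probe sets, 3.58% passed it. A simulated list of 18 genes lowered 2-fold reached percentile 0, and 7% of 200 unchanged lists fell outside the central 95%. Changed genes and the lowered list were drawn only from probe sets well above the floor, and no spread between cultures was simulated. The recovery rates therefore do not cover genes near the floor, and none of these rates covers differences between cultures.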

Results

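Expression was measured in 2 clones of mouse mesoangioblasts, D16 and D351, with 1 array per clone. Signals summed to 653854 on the D16 array and 646285 on the D351 array. Of the probe sets that were not controls, 6920 reached the floor of 16.8 on at least 1 array, 5509 did so on both and 5491 on neither. Both cultures came from embryonic dorsal aorta, and the labels name smooth muscle differentiation and stem cells as the subject. The comparison answers how the transcripts of one clone differed from those of the other. No array was replicated, so each difference is between 2 RNA samples and was not tested against culture-to-culture spread.

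Clone D351 had higher signals for a joint list of smooth muscle and actin cytoskeleton genes and for extracellular matrix genes. It also had higher signals for a list of Wnt pathway genes that holds receptors and antagonists alike. Clone D16 had higher signals for cell cycle genes. Among 24 measured smooth muscle and actin genes the median was 1.45-fold higher in D351, and among 29 Wnt pathway genes it was 1.48-fold higher. Matrix genes (21 measured) had a median 1.40-fold higher in D351, a call lost with the floor at the 75th percentile and with the floor reached on both arrays. The median of 18 cell cycle and replication genes was 2.16-fold lower in D351. With values raised to the floor, Itga11, a collagen-binding integrin subunit, had the largest ratio towards D351 among the named genes (at least 36.7-fold). Slc14a1, a urea transporter, had the largest towards D16 (at least 28.6-fold). Both are bounds, so their rank depends on the floor.

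In total 1192 probe sets (17.2% of those at the floor on at least 1 array) passed the 2-fold rule, 639 higher in D351 and 553 higher in D16. Where both arrays reached the floor the split was 433 and 434. Counted by gene, 467 of 4922 measured genes were at least 2-fold higher in D351 and 422 in D16, and the median log2 ratio of all measured genes was -0.01. Across probe sets at the floor on both arrays, the log2 signals of the clones correlated with a Pearson r of 0.809 and a Spearman rho of 0.791, over probe sets that are not independent replicates.

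**Figure D1:**
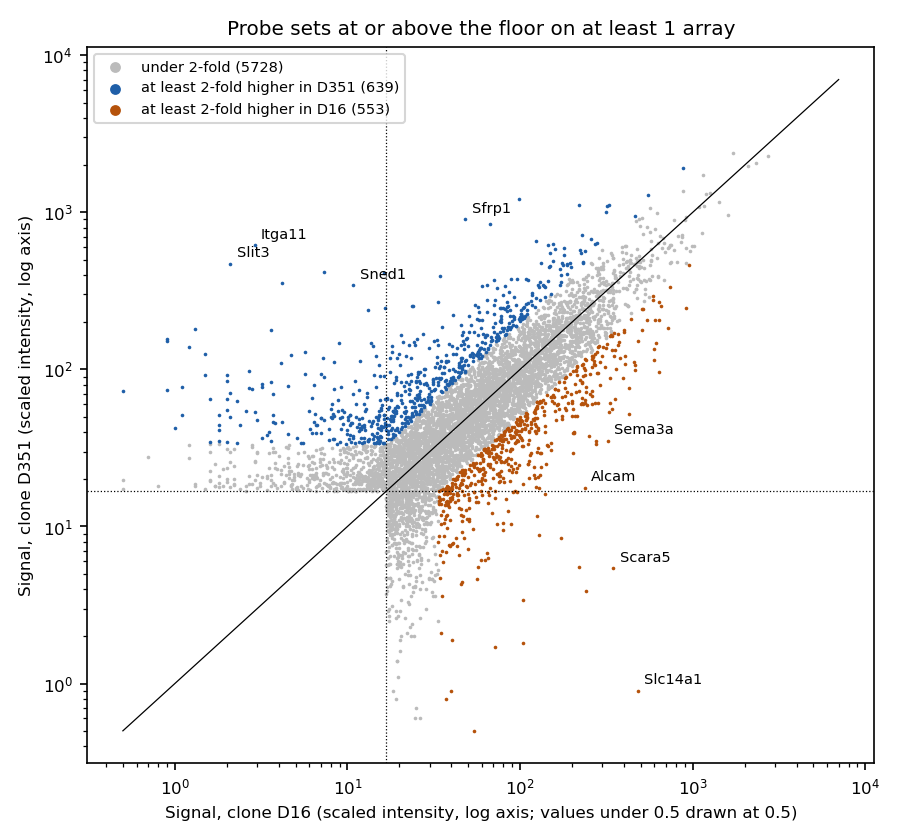
Signal of each probe set in clone D16 (horizontal, log axis) and clone D351 (vertical, log axis), in scaled intensity, for the 6920 probe sets at or above the floor (dotted lines) on at least 1 array. Blue points (639) are at least 2-fold higher in D351, orange points (553) at least 2-fold higher in D16, and the line marks equal signals.

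Among the 12 largest named differences towards D351, Itga11 read 2.9 in D16 and 617.2 in D351. Slit3, a secreted guidance ligand of Robo receptors, read 2.1 and 470.5 (at least 28.0-fold, on an _f probe set, a design shared by related transcripts), and Sned1, a matrix protein, read 10.8 and 342.8 (at least 20.4-fold). Sfrp1, a secreted Wnt antagonist, reached the floor in both clones, with 48.2 in D16 and 900.3 in D351 (18.7-fold). Aspn, a small leucine-rich matrix proteoglycan, was at least 10.6-fold higher, and Sulf1, an extracellular heparan sulfate sulfatase, at least 10.8-fold higher, with a log2 ratio of at least 3.05 on another probe set. The proprotein convertase Pcsk6 was at least 14.6-fold higher, and the muscle adherens junction protein Pgm5 at least 14.1-fold. F3, which encodes tissue factor, was 11.5-fold higher on an _f probe set. The lysosomal hydrolase Aga was 10.6-fold higher, the pro-apoptotic gene Pmaip1 at least 9.29-fold, and Cped1 at least 24.9-fold on an _s probe set, with a log2 ratio of at least 1.45 on an _r probe set.

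Towards D16, Slc14a1 read 480.6 in D16 and 0.9 in D351 on an _f probe set, with a log2 ratio of at most -3.85 on an _r probe set. Scara5, a scavenger receptor that binds ferritin, read 346.6 and 5.4 (at least 20.6-fold). Alcam, an adhesion molecule of the immunoglobulin superfamily, was 13.4-fold higher in D16 (236.7 against 17.7), with a log2 ratio of at most -1.95 on another probe set. Acot1, an acyl-CoA thioesterase, was at least 13-fold higher, and the microtubule-associated Map2 of neurons at least 10.3-fold. Another Map2 probe set was under the floor on both arrays (1.5 in D16 and 0.4 in D351), so the Map2 ratio rests on 1 probe set. The secreted semaphorin Sema3a was 9.16-fold higher in D16, at a log2 ratio of -3.20 and of -2.97 on another probe set. Ldlrad3 was 8.27-fold higher in D16, Klhdc8a 8.15-fold, Lmtk2 6.92-fold, and Prkg2, a cGMP-dependent protein kinase, 6.72-fold. Lpar2, a receptor for lysophosphatidic acid, was at least 7.48-fold higher. Ndc1, a nuclear pore protein, was 7.33-fold higher in D16 (log2 -2.87, and -1.99 on another probe set) and lies on chromosome 4 within a run of neighbouring genes that were mostly higher in D16. In 9 of the 12 genes towards D351 and 5 of the 12 towards D16 the dimmer array was under the floor. Of these 24 genes, 6 had another measured probe set, and it lay in the same direction in 6.

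Cell cycle and DNA replication genes were lower in D351 as a group. Of 18 measured members 10 were at least 2-fold lower, 0 were at least 2-fold higher, and Incenp alone had a ratio above 0 (log2 0.28, with -0.35 on another probe set). Ncapg, a condensin subunit, read 132.9 in D16 and 23.9 in D351 (5.56-fold). Bub1b, of the spindle checkpoint, was 4.48-fold lower in D351, the kinetochore motor Cenpe 3.63-fold and the phosphatase Cdc25b 3.48-fold. Foxm1, a transcription factor of mitotic genes, was 3.36-fold lower, and Gins1, of the replicative helicase, at least 3.39-fold lower. The list median (log2 -1.11) lay at percentile 0 among random lists.

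Smooth muscle and actin cytoskeleton genes had a median log2 ratio of 0.54 (percentile 99.99), with 8 of 24 measured genes at least 2-fold higher in D351 and 1 at least 2-fold lower. Mylk, the myosin light chain kinase of smooth muscle, was 7.04-fold higher in D351 (21.1 against 148.5), with a log2 ratio of at least 1.60 on a _g probe set. Palld, an actin-bundling scaffold, was 3.18-fold higher (log2 1.67, with 1.79 and 0.90 on other probe sets). The non-muscle myosin heavy chain Myh10 was 3.12-fold higher, and the focal adhesion protein Tns1 3.07-fold (log2 1.62, with 0.89 on another probe set). Tpm1 was 3.27-fold higher on its brightest probe set, but its other probe sets had log2 ratios of -0.15 and 0.02. Flnc, a filamin of muscle, went the other way, 4.10-fold lower in D351 on an _f probe set. Myh11, the smooth muscle myosin heavy chain, was close to equal (36.8 and 35.6), and the smooth muscle genes Myocd, Actg2, Kcnmb1, Synpo2, Ppp1r14a and Smtnl2 were under the floor on both arrays. Cald1 read 874.9 and 1357.6 (log2 0.63).

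Wnt pathway genes stood apart at percentile 100, with a median log2 ratio of 0.56, 9 of 29 at least 2-fold higher in D351 and 1 lower. Besides Sfrp1, the receptors Fzd6 (6.27-fold), Fzd5 (6.13-fold) and Fzd1 (2.63-fold) were higher in D351, as was Wls, the carrier of Wnt ligands for secretion (2.61-fold). Dkk3, of the Dickkopf family, was at least 5.04-fold higher. The receptor Fzd4 was the member past 2-fold in the other direction, with 122.4 in D16 and 48.8 in D351. Wnt2, Rspo3, Sfrp5, Wif1, Axin2, Nkd1 and Nkd2 were under the floor on both arrays. Because the list mixes receptors and antagonists, its median does not tell whether Wnt signalling itself was higher in D351. TGF-beta and BMP pathway genes (25 measured) had a median log2 ratio of 0.32 (percentile 98.3), with 3 at least 2-fold higher in D351 and 1 lower. Only 13 of the 25 were above 0, so the list went both ways. Its median was the lowest value above 0 (Skil), and the next lower was Tob2 at -0.01. The receptors Tgfbr1 (-0.62), Tgfbr2 (-0.81) and Tgfbr3 (-0.41) were below 0, while Bmpr1a (0.76) and Bmpr2 (0.58) were above. Fstl3, which binds activin, was at least 5.04-fold higher, the signal transducer Smad3 2.57-fold and Pmepa1 2.39-fold. The BMP antagonist Grem1 was 2.34-fold lower in D351. This list fell inside the random range when the floor was lowered (log2 0.01), when the mean replaced the median (0.18), and when each chromosome's median was taken off (0.23).

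Extracellular matrix genes had a median log2 ratio of 0.49 (percentile 99.6), with 8 of 21 at least 2-fold higher in D351 and 1 lower. Mmp23, a metalloproteinase, was 8.10-fold higher in D351, and Adamts5, an aggrecanase, was 5.07-fold higher (219.3 against 1111.6) with log2 ratios of 2.42 and 3.42 on other plain probe sets and 0.42 on a _g probe set. Fbn2, a microfibril protein, was at least 5.45-fold higher on an _r probe set, and Col5a2, a fibrillar collagen chain, at least 3.58-fold. Efemp1, a fibulin, was 4.15-fold lower in D351. The brightest member, Fbln5, read 1707.0 and 2389.6. The list fell inside the random range with the floor at the 75th percentile (log2 0.26) and among genes at the floor on both arrays (0.23).

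Markers of embryonic fibroblasts, the cell type of the feeder layer used during cloning, moved with these groups. The 6 measured markers had a median log2 ratio of 1.86 (3.62-fold, percentile 100), with 5 at least 2-fold higher in D351. These 5 were Sfrp1, Aspn and Col5a2, which also stand in the Wnt or matrix lists, together with the transcription factor Prrx1 (3.66-fold) and the stromal surface protein Cd248 (2.36-fold). Tcf4 was 2.65-fold lower on its brightest probe set (log2 -1.41) and had -0.59 on another, so that the median over its probe sets did not reach 2-fold. HOX genes stood apart on 5 measured members (median log2 0.99, percentile 99.5), with Hoxb2 3.42-fold and Hoxc5 at least 2.24-fold higher in D351, Hoxd9 at a log2 ratio of at least 0.99, and Hoxa3 (-0.84) and Hoxc10 (-0.30) below 0. Oxidative phosphorylation genes (6 measured) were lower in D351, with a median log2 ratio of -0.58 (percentile 2.33). Sdhb, a succinate dehydrogenase subunit, was 2.28-fold lower, and Cox6a1 (0.08, an _f probe set) was the member above 0. The HOX and oxidative phosphorylation calls were both lost with the floor at the 25th percentile and with the mean of the list (0.79 and 0.56 for HOX, -0.58 and -0.56 for oxidative phosphorylation).

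Of the 19 lists with at least 5 measured genes, these 8 stood apart, 6 with a median higher in D351 and 2 with a median higher in D16. Lists of randomly drawn genes would give 0.95, but genes of a list can vary together and lists share members such as Sfrp1. The excess over 0.95 therefore does not measure a difference beyond the spread between cultures. The other 11 lay inside the range of random lists. Among them, mesenchymal progenitor markers (9 measured, median log2 -0.40, percentile 6.35) went both ways. Alcam, Sdc4 (4.43-fold, an _s probe set), Gata4 (at least 3.23-fold) and Grem1 were higher in D16, and Hand2, a transcription factor of heart and limb mesenchyme, was 7.12-fold and Prrx1 3.66-fold higher in D351. Cardiac muscle markers (5 measured, -0.40, percentile 5.47) held Gata4 and, in the other direction, Tbx5, at least 2.92-fold higher in D351. Neural and neural crest markers (5 measured, -0.45, percentile 7.38) included Map2 and the neurofilament Nefl, at least 2.38-fold higher in D16. Pericyte and mural markers (5 measured, -0.37, percentile 20.4) included Cspg4, which encodes the proteoglycan NG2, 3.19-fold higher in D16. Endothelial markers (7 measured, -0.16, percentile 25.8) held Flt1, a VEGF receptor, at least 2.65-fold higher in D351, and Nrp2, 2.93-fold higher in D16.

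Notch pathway genes (17 measured) had a median log2 ratio of 0.28 (percentile 90.8), and Dlk1 was at least 4.11-fold lower in D351. Imprinted genes (9 measured, -0.28, percentile 12.8) included Dlk1 and, in the other direction, the neighbouring non-coding gene Meg3, at least 3.33-fold higher in D351 on one probe set and log2 at least 0.26 on another. Interferon response genes (17 measured, 0.25, percentile 93.9) included Bst2 (87.9 in D16 and 219.6 in D351) and Oasl1 (4.00-fold lower), and Parp12 had a log2 ratio of 1.32 on one probe set and at least 0.02 on an _r probe set. Cholesterol and fatty acid synthesis genes (19 measured, -0.33, percentile 5.91) included the sterol carrier Stard4 (3.60-fold lower in D351, log2 -1.85, with -0.94 on another probe set), Acsl3 (2.62-fold lower), Acacb (at least 2.07-fold lower) and Hsd17b7 (2.09-fold higher, an _i probe set). Chemokine and cytokine genes (13 measured, -0.07, percentile 36.4) included Cx3cl1, at least 2.38-fold lower in D351 on an _f probe set. Adipocyte genes (5 measured) had a median log2 ratio of 0.10 (percentile 62.2).

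Too few genes were measured in 7 lists for a placement. Sox9, a cartilage transcription factor and the 1 measured gene of its list, was 2.16-fold lower in D351 (log2 -1.11). Its other probe set had -0.49, and the median of both (-0.80) did not reach 2-fold. Of 3 skeletal muscle markers Fbxo32 was at least 2.57-fold higher and Met 2.14-fold lower in D351. Proteasome genes (4 measured) had a median log2 ratio of -0.39, the 1 ribosomal protein gene, Rpl27, at most -0.33, and 3 epithelial markers -0.51. Blood and macrophage markers (2 measured, Cd44 and Runx1) read -0.09 and 0.43. Of the sex-linked genes Kdm5c (-0.06, with at least 1.03 on another probe set) and Kdm6a (0.68, an _i probe set) were measured, and Xist and Kdm5d were under the floor on both arrays.

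**Figure D2:**
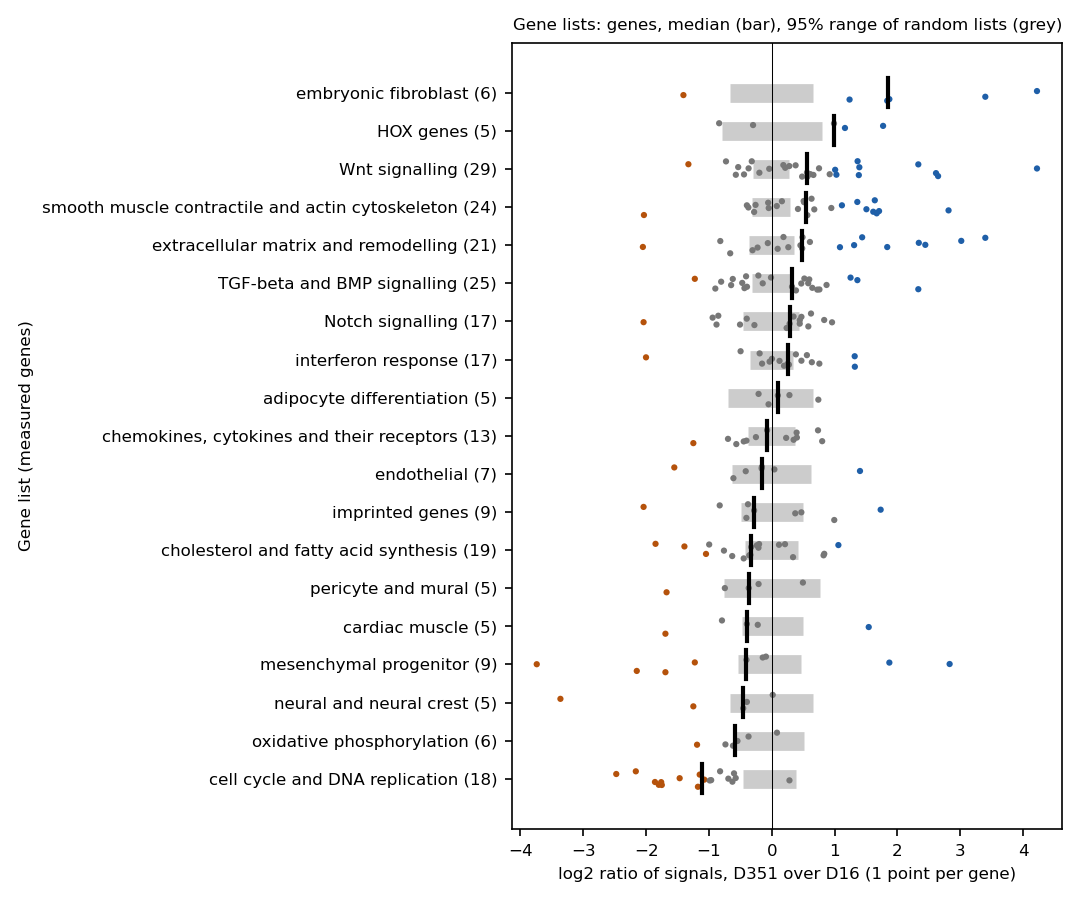
Log2 ratio of D351 over D16 for the measured genes of the 19 lists with at least 5 of them, 1 point per gene (blue at least 2-fold higher in D351, orange at least 2-fold higher in D16). Black bars are list medians and grey bands the central 95% of 10000 random lists, and the cell cycle median of -1.11 lies farthest below 0.

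Gene medians also differed between chromosomes. Of 20 chromosomes, 13 had a median outside the central 95% of random lists of the same size. Genes on the X chromosome (140 measured, median log2 0.39) and on chromosome 10 (250 measured, 0.35) were higher in D351, with 72.9% and 72.4% of their genes above 0 against 48.8% of all measured genes. Lower medians were found on chromosomes 4 (295 measured, -0.34), 18 (138 measured, -0.32), 17 (211 measured, -0.26) and 7 (302 measured, -0.22). Without a run of 62 neighbouring genes, chosen after the values were seen, the chromosome 4 median was -0.21. With the gene order divided in the middle, the medians of the first and second parts differed beyond shuffled gene order on 6 chromosomes (1, 4, 9, 10, 14 and 17). They were -0.63 and -0.15 on chromosome 4, -0.08 and 0.32 on chromosome 1, 0.55 and 0.22 on chromosome 10, and -0.37 and -0.12 on chromosome 17.

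**Figure D3:**
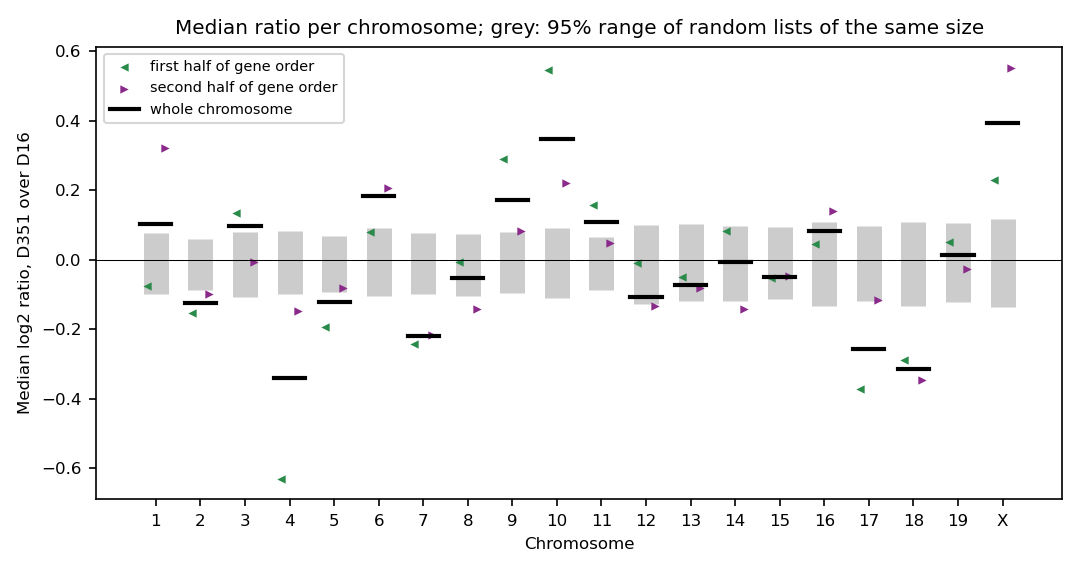
Median log2 ratio of D351 over D16 of the measured genes of each chromosome (black bars), with the medians of the first and second part of its gene order, divided in the middle (triangles) and the central 95% of random lists of the same size (grey). The X chromosome (0.39) and chromosome 10 (0.35) lie highest and chromosome 4 (-0.34) lowest.

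**Figure D4:**
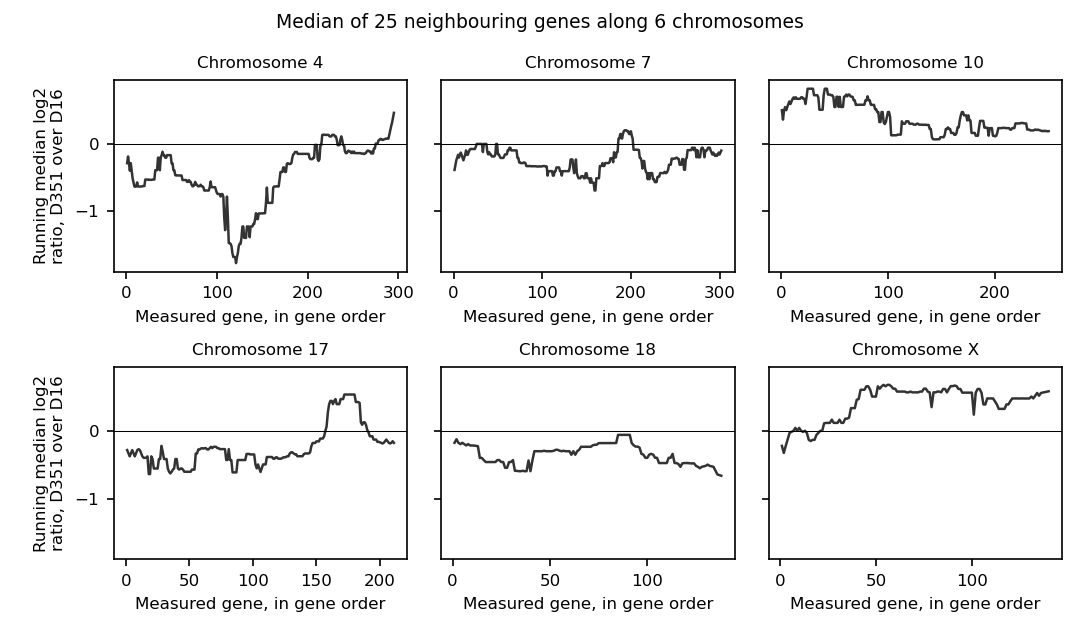
Running median of the log2 ratio of D351 over D16 over 25 neighbouring measured genes along the 6 chromosomes with the largest medians, in gene order and not to genomic scale, with fewer genes per value at the ends. On chromosome 4 the running median reached -1.76 within the run from Acer2 to Svbp.

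Single ratios could be set against another probe set for the same gene. Across 1113 genes with at least 2 measured probe sets, the ratios of the brightest pair correlated with a Pearson r of 0.614 (0.576 to 0.649) and a Spearman rho of 0.550. The SD of their difference was 0.71, which corresponds to 0.50 per probe set. Where the first probe set passed 2-fold (219 genes), the other lay in the same direction for 193, or 88.1% (Wilson interval 83.2 to 91.8%). Both passed 2-fold in the same direction in 89 genes and in opposite directions in 3. Both ratios of a pair come from the same 2 arrays. The comparison therefore covers probe design, but neither effects shared by the probe sets of an array nor differences between cultures.

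The BioB, BioC, BioDn and CreX control probe sets ending in _at, of which 9 reached the floor, had a median 1.44-fold higher in D16. Of these 9, 8 were higher there. This offset is about as large as the smooth muscle and actin, Wnt and matrix list medians (1.45-fold, 1.48-fold and 1.40-fold), which lie in the other direction. The signals were not rescaled to these controls, so all folds given here are relative to the bulk of each array. Among the controls ending in _st, weak signals of BioDn-3 (log2 -0.24) and BioDn-5 (-0.12) were higher in D16. CreX-3 was higher in D351 (at least 0.29). The ratio of 3' to 5' signal was 1.57 in D16 and 1.30 in D351 for beta-actin, and 1.41 and 1.09 for Gapdh.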

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

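No test was run on the following values, which were picked out after they were seen. They come from control probe sets left out of the comparison, and each differed more than 2-fold between the arrays with at least 1 bright signal. The control AFFX-MUR_b2_at read 486.6 in D16 and 110.5 in D351 (log2 -2.14). The control AFFX-MURINE_b1_at, among the brightest features of both arrays, read 6130.8 and 2838.1 (log2 -1.11). AFFX-MURINE_B2_at fell just short of 2-fold in the same direction, with 6716.8 in D16 and 3417.3 in D351 (log2 -0.97). In the other direction, AFFX-MurFAS_at read 23.1 in D16 and 123.6 in D351 (log2 2.42). The targets of these controls were not given in the sources used here.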

How the results depend on the processing

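The alternatives that took off chromosome medians, asked for the floor on both arrays, kept only plain _at probe sets, left out genes past 2-fold or left out the chromosome 4 stretch were chosen only after the data were seen. No list or chromosome that stood apart, and no named gene, reversed its direction under any alternative run for it. Probe sets past the size rule, higher in D351 and in D16, numbered 1223 and 1127 with the floor at the 25th percentile, 260 and 223 at the 75th, 1342 and 1314 with a 1.5-fold rule, and 224 and 171 with a 3-fold rule, as each rule admits more or fewer values. The pair of probe sets of a gene correlated at 0.519 with the lower floor and 0.721 with the higher one, and lay in the same direction in 79.3% and 94.6%. Across the alternatives at most 9 lists stood apart, against 8 with the main settings. Among lists inside the random range in the main settings, values reached -1.03 for cardiac muscle and -1.09 for neural markers. Lists standing apart numbered 5 with the higher floor and 4 with the floor reached on both arrays, both with fewer genes measured. Under these settings the matrix median was 0.26 and 0.23, inside the random range. With the lower floor, TGF-beta and BMP genes (0.00718), HOX genes (0.79) and oxidative phosphorylation genes (-0.58) fell inside it, and with the mean of the list the same lists did (0.18, 0.56 and -0.56), as TGF-beta and BMP genes did with chromosome medians taken off (0.23), and the cause was not tested. Cell cycle (-1.20 to -1.06), Wnt (0.44 to 0.66) and smooth muscle and actin genes (0.38 to 0.60) kept their direction and stayed outside the random range under all 11 alternatives, and embryonic fibroblast markers (1.48 to 1.86) under the 10 that gave a value. The 6 chromosomes with the largest medians did so under 9 alternatives, with 11 to 13 chromosomes apart. Their medians ranged from -0.38 to -0.16 (chromosome 4), -0.39 to -0.24 (18), -0.33 to -0.19 (17), -0.27 to -0.21 (7), 0.28 to 0.39 (10) and 0.20 to 0.45 (X), each nearest to 0 without genes past 2-fold. Over the scaling, floor and probe set alternatives, 436 values of named genes stayed past 2-fold and 18 did not, 13 of them with the higher floor, where 8 genes had no value, and 5 with the median over probe sets. No paired analysis was possible because each clone had 1 array. Weak signals limit single ratios, since those against a value under the floor are bounds.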

Other observations

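Several choices here were made only after the results were seen, namely the lists of further mitosis genes and of axon guidance genes, the search for gene stretches and its tests, the tests of copy differences and of feeder fibroblasts, and the restrictions to genes at the floor on both arrays, to genes under 2-fold and to ratios with chromosome medians taken off. Mitosis and replication genes outside the fixed list were lower in D351 too, with 60 of 139 listed genes measured, 24 at least 2-fold lower, 0 at least 2-fold higher and 54 below 0. Ckap2l, a spindle protein, was 6.12-fold lower, Esco2, an acetyltransferase of cohesin, at least 5.74-fold, Depdc1b 5.62-fold, Ncapg2, a condensin subunit, 5.46-fold and the mitotic kinase Pbk 5.20-fold. Spag5 (4.42-fold), Kif15 (4.15-fold, an _f probe set), a mitotic kinesin, and the midbody protein Cep55 (4.01-fold) followed.

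Axon guidance ligands and receptors went both ways, with a median log2 ratio of 0.01 over 26 of 87 listed genes (percentile 56.5), 3 at least 2-fold higher in D351 and 7 lower. Slit3 (an _f probe set), Srgap2 (at least 4.39-fold) and the netrin receptor family member Neo1 (3.68-fold) were higher in D351. Higher in D16 were Sema3a, its relative Sema3c (at least 2.15-fold, an _i probe set), the semaphorin receptor Nrp2, the ephrins Efna5 (3.25-fold) and Efna3 (3.01-fold), the teneurin Tenm4 (at least 6.15-fold) and Alcam.

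A run of neighbouring genes on chromosome 4, from Acer2 to Svbp, was higher in D16, with a median log2 ratio of -1.15 over 62 measured genes (2.22-fold), 35 at least 2-fold lower in D351 and 3 higher (Tceanc2, Podn and Dmrta2). Its ends were set by the windows of 25 genes and are not resolved to single genes. Acer2 itself was slightly higher in D351 (17.1 in D16 and 19.2 in D351). The run included Mier1 (908.8 in D16 and 245.1 in D351), Eif2b3, of a translation initiation factor (424.8 and 76.5), and the heme synthesis enzyme Urod (483.1 and 151.3, an _f probe set). A chance run is argued against by the lowest running median of 25 genes, -1.76, against at most 1.06 in size in 1000 shuffled gene orders, and errors of single probe sets by the 13 other probe sets of these genes, whose median was -1.14 with 12 below 0. More copies of this stretch in D16, or fewer in D351, stay open with no value that decides: 44 of the 50 genes at the floor on both arrays (88.0%) were lower in D351, but the stretch was picked for its low median. DNA was not measured, and a shared regulation of the stretch was not tested.

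The chromosome medians kept their side of the random range on 6 of the 6 leading chromosomes after the loess correction and among genes at the floor on both arrays, which argues against intensity-dependent bias and against weak values near the floor as their whole cause. Both parts of the gene order lay apart in one direction on 5 of these chromosomes (4, 7, 10, 18 and X). On chromosomes 7, 10, 18 and X this argues against a local cluster of co-expressed genes as the whole cause. On chromosome 4 the parts do not decide, because the run above crosses the middle of the gene order and lies in both. The run carries part of the chromosome 4 shift (-0.34, and -0.21 without it). The second part of chromosome 4 lay only just outside the range (-0.15). A cluster stays open for chromosomes 4 and 17. Local co-expression of adjacent genes stays open, as directly adjacent genes correlated at 0.147, above the 0.03 to 0.09 of shuffles within chromosomes. Genes 5 places apart (0.0791) lay inside that range. This does not show that the excess was short, since the correlation was no lower at 20 places (0.0864) and the chromosome 4 run spans 62 genes. What local co-expression adds to the medians was not tested. The correlation of genes 20 places apart does not decide it: at 0.0864 it lay above shuffles across all chromosomes (at most 0.03) but inside the 0.03 to 0.09 within chromosomes, so it restates the chromosome medians and the range chosen for the test beforehand was the wrong one. A different number of copies of whole chromosomes or large parts stays open, as 6 of 6 medians stayed apart without genes past 2-fold but moved towards 0 (chromosome 4 to -0.16, X to 0.20), which any broad shift would give and which does not single out copies. For a copy difference equal along the whole chromosome, the first and second parts differed beyond shuffled order on 3 of them (4, 10 and 17). This does not decide against it. Shuffling breaks up any local co-expression, and a local run on top of an equal copy difference would also make the parts differ. Copy number was not measured.

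Lower cell cycle and higher Wnt, matrix and smooth muscle and actin genes in D351 are not explained by chromosome shifts acting through the list genes alone, since 4 of 4 lists stayed outside the random range with chromosome medians taken off. Scaling or weak values left 3 of the 4 lists apart under the least favourable scaling or floor setting, so for the matrix list weak values stay open. A difference in proliferation between the cultures stays open: the further mitosis genes had a median log2 ratio of -0.81 (1.75-fold lower in D351), but they belong to the same programme on the same arrays and were listed after the first list was seen, so they restate it. More feeder fibroblasts in the D351 culture could lower cell cycle signals and raise matrix signals alike. Mitomycin C kept these cells from dividing, and growing clones were moved off them to gelatin-coated dishes and expanded, which would dilute them. Of the 6 listed fibroblast markers 5 were higher in D351, and Tcf4 was lower (log2 -1.41 and -0.59 on its probe sets). Whether Tcf4 marks fibroblasts in these cultures was not tested. The D16 culture also had signals for other listed markers, such as Cd248 (238.9) and Prrx1 (149.3). For this reason more feeder fibroblasts cannot be told apart from a difference between the clones. That biological difference between D16 and D351 remains open and untested, as each clone had 1 culture on 1 array.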
